A study of Mus musculus with 2 samples.

How the data were processed

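Total RNA from 2 cultures of RAW246.1 mouse macrophage cells grown in DMEM was labelled with Cy3 and hybridised to Agilent mouse arrays, per the labels' protocols, with 1 array for PBS and 1 for miR-122. The extraction text of the labels names RIPA buffer, while the molecule is given as total RNA; how the RNA was purified is not given in the sources used here. Groups were taken from the source name of each sample.

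The deposited scanner files hold spot intensities made with Agilent Feature Extraction 11.0.1.1, per the file headers: background-subtracted and detrended intensities with no normalization between arrays, and the median spot and local background intensities. The deposited series matrix holds processed log2 values by the authors, whose normalization is not given in the sources used here. Both of its columns have the same distribution and a median of 5.16, as after quantile normalization. Each column correlated across probes at 0.997 with the log2 scanner signal of its own array and at 0.985 with that of the other array, so its scale is log2, it is not centred by gene, and its columns run as labelled.

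Each array held 44397 spots, of which 1377 were controls and were left out. Spots flagged as non-uniform or as population outliers were left out, 145 non-control spots on the PBS array and 196 on the miR-122 array. Well above background were 71.9% of the non-control spots on the PBS array and 70.1% on the miR-122 array, by the flag of the scanner software. The processed signal was converted to log2, the spots of a probe were averaged, and the 75th percentile over non-control probes was subtracted on each array; before this step the 75th percentiles differed by -0.28 and the medians by -0.10, miR-122 minus PBS.

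The files give accessions for probes. They were matched without versions to a RefSeq gene table of assembly GRCm38.p6, used for names only, and 27234 of 39429 probes matched 20659 gene symbols. A gene took its brightest probe among those well above background on at least 1 array. This left out 20 genes that had probes well above background on both arrays, but whose brightest probe was so on 1 array only. Probes of 1 gene can disagree: of 201 genes with several probes and at least a 2-fold difference, 40 had probes that differed in opposite directions. For genes well above background on 1 array only, the bound sets the value on that array against the higher of the lowest signal well above background on the other array and the probe's own signal there.

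With 1 array per group no test was run. Genes were counted by a fixed size of at least 2-fold. The median difference of each of 25 gene lists and 9 lists of markers of other cell types was given as a percentile among 10000 random lists of the same size drawn within 10 bins of the mean level. The lists, the counting rule, most alternatives and the rule for named genes were fixed before the data were examined, and the alternatives added afterwards are named as such in the closing section. The rule names, among genes on both arrays with an established symbol and probes that differ in the same direction, the 10 with the largest positive and the 10 with the largest negative differences, up to 4 members with the largest absolute difference in a list that is described, the 5 largest bounds in each direction, and Actb, Gapdh, Hprt and Tlr7. Genes outside the rule are said to be so where they are named, and 1 gene that the rule takes is not reported here. The list of reported miR-122 targets was written from general knowledge. A planned comparison of genes with and without miR-122 seed sites was not run, because 3' UTR sequences were not used here.

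Alternatives were median scaling, quantile normalization, loess on the mean level with a span of 0.3, normexp background correction with an offset of 50, the authors' log2 values, other filters on dim probes, the mean over probes of a gene, flagged spots kept, and thresholds of 1.5-fold and 4-fold. The normexp alternative used median spot intensities because the mean spot intensity is not among the columns used here. Scanner signals were read and normalized with R 4.3.3 and limma 3.58.1, and gene tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

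The counting step was tested on simulated data for the miR-122 minus PBS comparison over 15781 genes, with the spread between replicate spots as the only noise. Of 40 genes given a log2 difference of 1.5, 95.0% passed 2-fold, as did 95.0% of 40 given -1.5 and 100% of 40 given 3.0. Of 40 genes given 0.7, 2.50% passed, and 0.359% of 15581 unchanged genes passed. Of 60 random lists of 30 unchanged genes, 90.0% had a percentile between 5 and 95. This noise leaves out any spread between cultures. Simulated genes kept the background flag of the PBS array, so the loss of a lowered gene to background was not simulated.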

Results

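Gene expression was measured on 2 one-colour Agilent mouse arrays hybridised with Cy3-labelled RNA from RAW246.1 cells, which the labels describe as macrophages. One culture had received PBS, the mock treatment, and the other synthetic miR-122, a microRNA made mainly by hepatocytes, at a stated dose of 5 μg/mL. The comparison bears on a reported effect of liver-derived miR-122 on the inflammatory activation of alveolar macrophages, which these arrays do not test. The cells were cultured RAW246.1 cells given synthetic miR-122, so alveolar macrophages and liver-derived miR-122 were not measured. Each group held 1 array, so no difference given here has a replicate check, a p-value or a standard deviation between cultures. The title of the sample described as miR-122 treated reads as if the microRNA had been left out, and the treatment text is the same for both samples. The array labelled miR-122, by its source name and description, is called the miR-122 array, and directions rest on that label, which no gene in the data checks. Both arrays lay on the same slide, so slide does not separate them, but array position and treatment cannot be told apart.

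Of 39429 non-control probes, 28306 were well above background on the PBS array and 27573 on the miR-122 array, and no spot was saturated. Among 282 probes printed 10 times and well above background on both arrays, the median standard deviation of the log2 signal over the spots was 0.05 on the PBS array and 0.06 on the miR-122 array. Different probes of the same gene gave log2 differences with a pooled standard deviation of 0.30. These values describe technical precision within an array, and the number of arrays limits the precision of each comparison. Levels are log2 signals relative to the 75th percentile of their array, and differences are miR-122 minus PBS.

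The genes highest on the miR-122 array relative to PBS encoded interferon beta, inflammatory mediators and interferon-inducible proteins. Ifnb1, which encodes interferon beta, had a level of -3.81 on the PBS array and 3.21 on the miR-122 array, 131-fold higher. The chemokine gene Cxcl10 was 70.7-fold higher and the cytokine gene Il6 was 68.5-fold higher. Cmpk2, a mitochondrial nucleotide kinase gene, was 46.5-fold higher, Ccl5 was 45.6-fold higher, Rsad2, which encodes the antiviral protein viperin, was 37.4-fold higher, and Hdc, which encodes the enzyme that makes histamine, was 34.9-fold higher. Gbp2, Gbp2b and Ifit1bl1 were 47.5-fold, 43.7-fold and 43.6-fold higher, with the limit that these genes belong to families of close relatives whose transcripts a probe may share. Folds of genes that were dim on an array depended on the background correction: with normexp, Ifnb1 was 44.2-fold, Il6 23.4-fold, Gbp2 27.4-fold, Gbp2b 26.9-fold, Ifit1bl1 9.85-fold and Hdc 8.85-fold higher. The genes lowest on the miR-122 array included S100a7l2, 8.53-fold lower, and several genes of DNA synthesis and mitosis. Tk1, which encodes thymidine kinase, was 5.40-fold lower, Aunip 5.40-fold, Ankle1 5.13-fold, the DNA glycosylase gene Neil3 4.93-fold, the repressor gene E2f8 4.91-fold, the spindle gene Ska1 4.86-fold, the ribonucleotide reductase gene Rrm2 4.62-fold, the cyclin gene Ccna2 4.52-fold and Pbk 4.39-fold lower. With normexp, S100a7l2, whose level of -4.76 on the miR-122 array was close to the lowest level well above background, was 2.15-fold lower, Aunip 2.55-fold, Ankle1 3.32-fold, Neil3 2.10-fold, Ska1 2.33-fold and Ccna2 2.46-fold lower. The mean over the probes of Ankle1 was 2.77-fold lower.

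Of 15022 named genes well above background on both arrays, 687 were at least 2-fold higher and 268 at least 2-fold lower on the miR-122 array, so 71.9% of the genes past 2-fold were higher. At 4-fold, 0.812% of the genes were higher and 0.113% lower. The median difference over all 15022 genes was 0.09, and scaling each array on its median instead moved it by -0.18. With that scaling 471 genes were at least 2-fold higher and 456 at least 2-fold lower, and 50.8% were higher, while quantile normalization, which moved the median by -0.12, gave 529 and 354 genes and 59.9%. Normexp gave 388 and 143 genes, and kept 56.5% of the genes counted as higher and 52.2% of those counted as lower. Without a filter on dim probes, 1358 genes were at least 2-fold higher and 451 at least 2-fold lower.

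**Figure D1:**
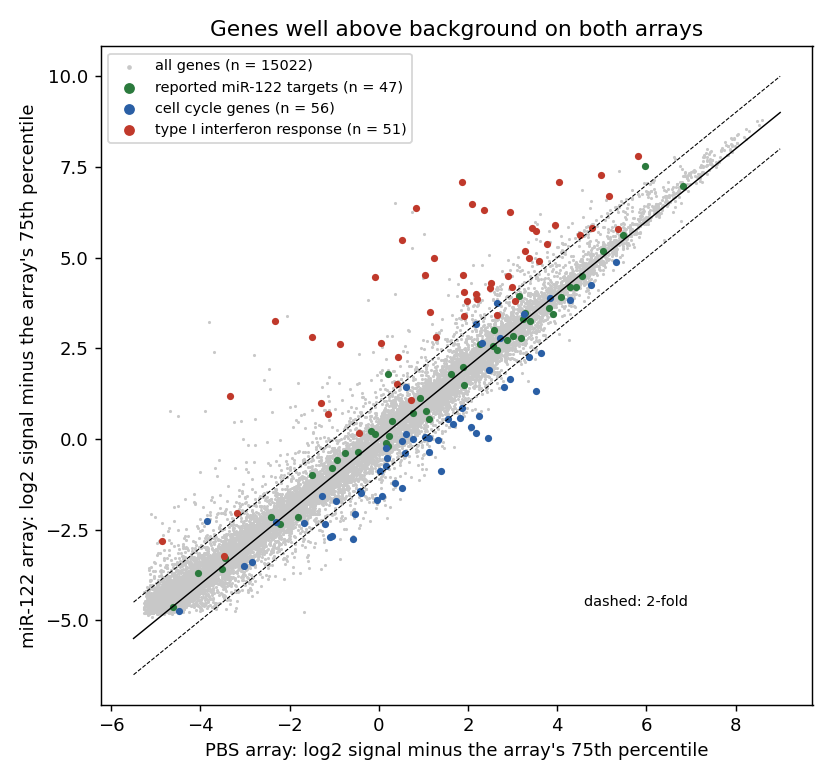
Level of each of 15022 genes on the PBS array (horizontal axis) and the miR-122 array (vertical axis), as log2 signal minus the 75th percentile of the array; the solid line marks equal levels, the dashed lines 2-fold differences, and each point is 1 gene on 1 array per group. Of the 51 interferon response genes, 45 lie above the upper dashed line, and 26 of the 56 cell cycle genes lie below the lower one.

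Interferon-stimulated genes were higher on the miR-122 array as a group. All 51 measured genes of the type I interferon response list had positive differences under the scaling used, 45 of them at least 2-fold, with a median difference of 1.90. The list included Gbp2, Cmpk2, Rsad2 and Gbp3, the last 31.4-fold higher. Its median lay at percentile 100 among 10000 random lists of the same size and level, which is a description of these 2 arrays and not a test. Among 23 genes for sensing of nucleic acids and antiviral RNA decay, 13 were at least 2-fold higher and 0 at least 2-fold lower, with a median 2.14-fold higher at percentile 100. Of these 23 genes, 10 also belong to the interferon list, and the median of the rest was 0.44. Zbp1, a sensor of Z-form nucleic acids, was 11.2-fold higher, the RNA sensor gene Ifih1 5.24-fold, Ifi204 4.93-fold and the DNA exonuclease gene Trex1 3.81-fold higher. In the list for antigen presentation by class I molecules, 10 of 22 genes were at least 2-fold higher and the median was 0.98 at percentile 100. The immunoproteasome genes Psmb10 and Psmb9 were 5.58-fold and 5.47-fold higher, the peptide transporter gene Tap1 5.36-fold, or 3.32-fold with normexp, and H2-T10 4.79-fold higher.

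Inflammatory cytokine genes were also higher as a group, with 9 of 18 measured members at least 2-fold higher, 0 at least 2-fold lower and a median of 1.19 at percentile 100. Besides Ifnb1 and Il6, Csf1, a macrophage growth factor gene, was 13.2-fold higher, or 6.06-fold with normexp, and Il18 6.44-fold higher. Tnf and Il1b, cytokine genes whose probes are printed 10 times and which were named after their values were seen, differed by 1.49 and 0.99, and the spots of each probe varied by standard deviations between 0.02 and 0.05 on either array. Chemokine genes had a median of 0.48 at percentile 99.9, and 5 of 18 were at least 2-fold higher, among them Ccl7, 5.83-fold higher, and Ccl2, 2.94-fold higher. In the list of NF-kB subunits, regulators and targets, 31 of 33 genes had positive differences but 3 were at least 2-fold higher, with a median of 0.47 at percentile 100. Cd40 was 18.5-fold higher, or 10.3-fold with normexp, Nfkbiz 2.62-fold, Tnfaip3, a feedback inhibitor, 2.08-fold, and Traf1 1.94-fold higher. Nfkbiz was under 2-fold with normexp, and Tnfaip3 with median scaling, quantile normalization and the authors' values. Immediate early genes had a median of 0.81 at percentile 100, with 15 of 36 at least 2-fold higher and 1 at least 2-fold lower. Sgk1 was 5.00-fold higher, Csrnp1 2.91-fold, and Dusp6 and Atf3 both 2.86-fold higher. The differences were positive for 30 of these genes and negative for 6. Among the 6, Egr2 and Fos, named after their values were seen, were 2.50-fold and 1.86-fold lower. In the Toll-like receptor list, 2 of 34 genes were at least 2-fold higher and the median was 0.26 at percentile 99.9. Tlr3, the receptor for double-stranded RNA, had a difference of 3.58, or 2.50 with normexp, the adaptor gene Myd88 was 2.13-fold higher, or 1.89-fold with median scaling, Irf5 1.91-fold and Pik3ap1 1.74-fold higher. Tlr7, the endosomal receptor for single-stranded RNA, differed by 0.78.

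**Figure D2:**
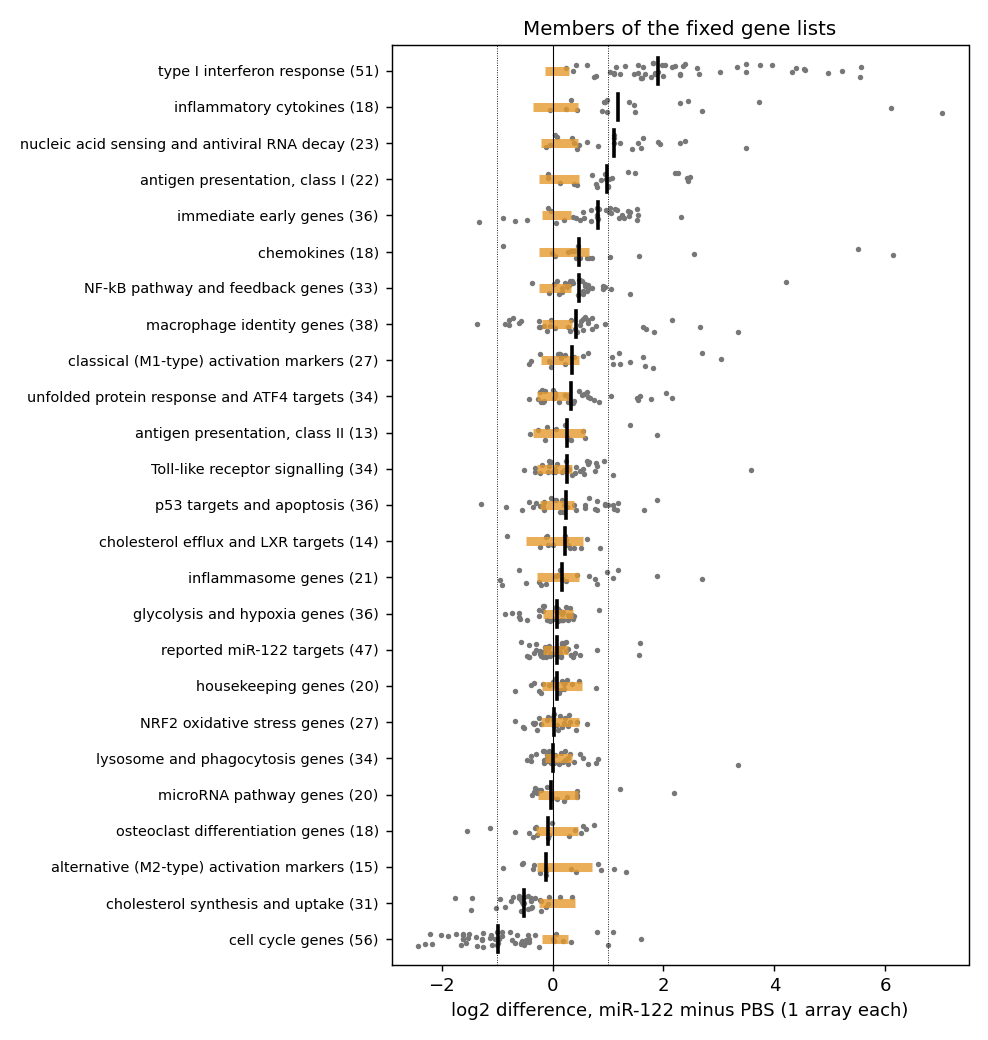
Log2 difference, miR-122 minus PBS, of each measured member (grey points) of the 25 gene lists, with the number measured in parentheses; the black bar is the median of the list and the orange band the range of the medians of 10000 random lists of the same size and level. The interferon response list has the highest median, 1.90, and the cell cycle list the lowest, -0.99.

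Genes of proliferating cells were lower on the miR-122 array. In the cell cycle list, 26 of 56 measured genes were at least 2-fold lower and 2 at least 2-fold higher, with a median of -0.99 at percentile 0. The members with the largest differences were Tk1, E2f8, Rrm2 and Ccna2. Ccnd2 and Ccnd1, the 2 members at least 2-fold higher and named after their values were seen, encode G1 cyclins and were 3.03-fold and 2.14-fold higher; Ccnd2 was under 2-fold with normexp, and Ccnd1 with median scaling, quantile normalization and the authors' values. Genes of cholesterol synthesis and uptake had a median of -0.51 at percentile 0, and 29 of 31 had negative differences, 4 of them at least 2-fold lower. The desaturase gene Scd2 was 3.40-fold lower, the fatty acid elongase gene Elovl6 2.79-fold and Cyp51 2.74-fold lower. Liver X receptor targets and efflux genes had a median of 0.23 over 14 genes, at percentile 92.9, with none past 2-fold. Genes of the unfolded protein response and ATF4 pathway had a median of 0.33 at percentile 100, with 7 of 34 at least 2-fold higher, including Ddit3, 4.46-fold or 2.76-fold with normexp, Chac1, 4.11-fold, and Ppp1r15a, 3.43-fold higher. In the list of p53 targets and apoptosis genes, 6 of 36 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 0.25 at percentile 99.8. The differences were positive for 25 and negative for 11, and the median was 0.07 at its lowest over the scalings. Casp4 was 3.69-fold, Fas 3.13-fold and Casp1 2.25-fold higher, and Sesn1 was 2.44-fold lower. Casp1 was just under 2-fold with median scaling, quantile normalization and the authors' values. Casp4 and Casp1 also belong to the list of inflammasome genes.

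Macrophage activation and lineage genes went both ways. Markers of classical activation had a median of 0.35 at percentile 99.8, with 10 of 27 at least 2-fold higher. Cd69, dim on the PBS array, was 8.24-fold higher, or 2.32-fold with normexp. Edn1 was 6.47-fold, the inducible nitric oxide synthase gene Nos2 3.51-fold and the tissue factor gene F3 3.16-fold higher. On the PBS array Nos2 already had a level of 4.75, against -1.16 for Edn1 and -1.49 for F3. Nos2 was not alone in this. Acod1 and Tnf, named after their values were seen, had levels of 6.63 and 4.09 there, and Ccl2 had 5.98. Ifnb1 and Il6 were dim there, at -3.81 and -3.70. Whether the PBS culture was itself stimulated was not tested. Markers of alternative activation had a median of -0.12 at percentile 1.44 and a mean of the opposite sign. Of the 15 markers, 6 had positive and 9 negative differences, among the latter Ppargc1b, 1.87-fold lower. At least 2-fold higher were 2, Il4ra by 2.51-fold and the mannose receptor gene Mrc1 by 2.15-fold. With normexp both were under 2-fold, Il4ra at 1.95-fold and Mrc1 at 1.62-fold, and Mrc1 was also under 2-fold with the other scalings. Macrophage identity genes had a median of 0.43 at percentile 100, with 6 of 38 at least 2-fold higher and 1 at least 2-fold lower. They did not move together, with 24 positive and 14 negative differences. The Fc receptor genes Fcgr1 and Fcgr4 were 10.1-fold and 6.28-fold higher, and Maf and Laptm5 4.44-fold and 3.54-fold higher; with normexp, Fcgr1 was 5.25-fold and Maf 2.46-fold higher. Among the 14, Cx3cr1, Lyz2 and Adgre1, named after their values were seen, had differences of -1.36, -0.71 and -0.58. Also outside the naming rule, Itgam, Itgax and Csf1r had differences of -0.85, -0.78 and -0.78, and Lyz1 -0.02. Another probe of Itgam differed by 0.36, and another of Csf1r by -0.06. Class II antigen presentation genes had a median of 0.26 over 13 genes, at percentile 92.3, with 9 positive and 4 negative differences. The inhibitory ligand gene Cd274 was 3.71-fold and the costimulatory gene Cd86 2.64-fold higher, the latter 1.76-fold with normexp. Of the 13 genes only these 2 were past 2-fold, and neither encodes a class II chain. The list also held 2 genes that were well above background on the PBS array only, and both were lower on the miR-122 array. The class II gene H2-Eb2 was at least 4.51-fold lower. H2-DMb1, outside the naming rule, was lower by a bound under 2-fold. The chain genes H2-Aa, H2-Ab1 and H2-Eb1, named after their values were seen, differed by 0.26, 0.07 and 0.34. Inflammasome genes had a median of 0.17 over 21 genes, at percentile 87.7, whose sign turned with median scaling, and 4 were at least 2-fold higher, among them Gsdmd, 2.13-fold, or 1.88-fold with median scaling. Osteoclast genes had a median of -0.09 over 18 genes, at percentile 7.35, with Acp5 2.91-fold and Nfatc1 2.19-fold lower, the latter 1.91-fold as the mean over its probes. Lysosome and phagocytosis genes had a median of 0.01 over 34 genes, at percentile 15.9, a median whose sign turned under other scalings.

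Genes reported in the literature as repressed by miR-122 were not lower as a group. The 47 measured targets had a median difference of 0.08 at percentile 68.0, and 24 had positive and 23 negative differences. The sign of this median turned under other scalings, between -0.09 and 0.08. Among these targets 2 were at least 2-fold higher, Nt5c3 with a difference of 1.58 and Ccl2 with 1.56, and none was 2-fold lower; the negative member with the largest difference was Cux1, 1.49-fold lower. Genes of the microRNA pathway had a median of -0.02 over 20 genes, at percentile 18.7. The sign of this median turned with normexp and in the mean of the members. The helicase gene Mov10 was 4.54-fold and the RNA editing gene Adar 2.31-fold higher. Adar also belongs to the interferon list, and the median of the microRNA pathway genes without it was -0.03. Oxidative stress genes controlled by NRF2 had a median of 0.02 over 27 genes at percentile 16.4, glycolysis and hypoxia genes 0.09 over 36 genes at percentile 61.4, and housekeeping genes 0.07 over 20 genes at percentile 39.5, each with 0 genes past 2-fold and a median whose sign turned under other scalings. Of the reference genes, Actb differed by 0.21, Gapdh by 0.18 and Hprt by -0.25, and the signs of Actb and Gapdh turned under other scalings.

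The lists of markers of 9 other cell types had median differences between 0.02 and 0.58. Dendritic cell markers had a median of 0.58 over 7 genes, at percentile 99.1, with Zbtb46 8.51-fold, or 3.42-fold with normexp, and the interferon-inducible gene Bst2 3.07-fold higher. Endothelial markers had a median of 0.56 over 7 genes, also above nearly all random lists, and the highest level of any of them on the miR-122 array was -0.23. The medians were 0.39 for 7 B cell, 0.35 for 9 neutrophil, 0.35 for 13 hepatocyte, 0.25 for 7 fibroblast, 0.16 for 4 erythroid, 0.11 for 7 epithelial and 0.02 for 10 T cell and NK cell markers, and the last 3 changed sign between scalings. Over all genes, the median difference was 0.34 in the dimmest of 10 bins of level.

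Genes well above background on 1 array only have a bound in place of a fold. There were 457 such genes on the miR-122 array, 112 of them higher by a bound of at least 2-fold, and 739 on the PBS array, 30 of them lower by such a bound. The complement gene Cfb was at least 29.2-fold higher on the miR-122 array, Ifi213 at least 26.1-fold, the chemokine gene Ccl12 at least 19.7-fold, Tnfsf10, which encodes the death ligand TRAIL, at least 13.5-fold, and Tnfsf15 at least 8.71-fold higher. Plpp4 was at least 7.55-fold lower, Fibin at least 7.13-fold, Evc at least 6.68-fold, the class II gene H2-Eb2 at least 4.51-fold and Glt28d2 at least 4.03-fold lower.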

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

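The tests of neighbouring spots were chosen before their results were seen; the tests of scaling, of near-identical copies, of other cell types, of cultures and of targets without inducible members were chosen after the values they rest on had been seen.

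Probes whose accession matched no gene symbol lie outside the counts of named genes, and some of them differed strongly between the arrays. Of 7164 such transcripts well above background on both arrays, 45 were at least 4-fold higher on the miR-122 array and 2 were at least 4-fold lower. The largest difference, 6.62, was that of NM_010846, with a level of -3.72 on the PBS array and 2.91 on the miR-122 array.

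Interferon response genes were higher on the miR-122 array, with a median difference of 1.90 over 51 genes. A local defect of the array surface would raise nearby spots too, but 6337 measurements of spots within 6 rows and columns of these probes had a median difference of 0.11. This pooled median argues against a defect under most members, but it would not show a defect under a few. Other scalings left the median of the interferon list at 1.72 or more, which argues against a trend with level or the scaling as the cause. Probes shared between near-identical paralogs are argued against by the 26 members outside families with such copies, whose median was 1.81. A difference between the cultures other than miR-122, such as a contaminating stimulus, a response to any synthetic RNA or a wrong label, remains open: with 1 array per group and no control RNA it cannot be told apart from an effect of miR-122, which may also explain the pattern.

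Cell cycle genes were lower on the miR-122 array, with a median of -0.99 over 56 genes. Spots near their probes had a median difference of 0.10 over 7699 measurements. This pooled median argues against a surface defect under most members, but it would not show a defect under a few. Among median scaling, quantile normalization and loess the list median nearest to 0 was -0.98, and with normexp it was -0.84. The choice among these settings thus does not account for the pattern. RNA from cells of another type would bring their markers up, and the highest median over the 9 marker lists, without members of the interferon list, was 0.56 over 7 dim endothelial genes. A difference in growth or density between the cultures, or an effect of the treatment, may explain the pattern, and neither was tested.

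Reported miR-122 targets were not lower as a group. Induced members could hide a repression of the rest, so members of the cytokine, chemokine, NF-kB, interferon, immediate early and cell cycle lists were left out. This took out Ccl2 and Klf6 but kept Nt5c3, the target with the largest positive difference, 1.58. The 45 remaining targets had a median at percentile 18.7 of matched random lists, against 68.0 for all 47. The percentile thus moved far with 2 genes, and it neither shows nor excludes a small repression. A test on seed sites was not run.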

How the results depend on the processing

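No paired analysis was possible because each group holds 1 array, and for the same reason leaving out an array or fitting a slide block was not possible. The alternatives chosen after seeing the data were genes with all probes past 2-fold, bounds included in the cytokine list, the 2 ways of leaving out interferon genes with relatives, and targets without inducible members. The causes of the shifts were not tested, except that thresholds and filters change which genes count by construction.

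Over 143 named genes and their alternatives, 1299 of 1364 values moved by less than the spread between probes of a gene and 65 moved more; 8 values, of Actb, Gapdh and Slc4a1, had the opposite sign. Folds of 22 named genes moved by over 1.5 times with normexp, and that of 1, Ankle1, with the mean over probes. Of 76 named genes at least 2-fold different, 11 were under 2-fold in some alternative. Over 34 list medians, 221 of 371 values moved by less than the spread of random lists of that size and the rest moved more; 43 values over 11 lists had the opposite sign. Genes at least 2-fold higher numbered 687 and lower 268. The lower count was 456 with median scaling. Normexp gave 388 and 143 genes, no filter on dim probes 1358 and 451, and the upper part of the levels 384 and 130. Past 2-fold were 4.57% of the genes tested as higher and 1.78% as lower; the 1.5-fold threshold gave 12.1% and 5.99%, and the 4-fold threshold 0.812% and 0.113%. The share of higher genes, 71.9%, was 50.8% with median scaling, 59.9% with quantile normalization and 59.9% with the authors' values. Median scaling kept 68.6% of the genes counted as higher and 100% of those counted as lower.

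The interferon median, 1.90, was 1.72 with median scaling, 1.76 with quantile normalization, 1.84 with loess, 1.80 with normexp, 1.75 with the authors' values and 2.33 as a mean. It was 2.12 over 6 members with a symbol stem of their own and 1.81 without families of near-identical copies. The cytokine median, 1.19, was 1.01 with median scaling, 1.07 with quantile normalization and with the authors' values, 0.93 with normexp, 1.37 with flagged spots kept, 1.48 for genes on at least 1 array, 1.38 with no filter, 0.99 in the upper part of the levels, 1.91 as a mean and 1.40 with bounds. The cell cycle median, -0.99, was -1.16 with median scaling, -0.84 with normexp and -0.88 as a mean. The median of reported targets, 0.08, reversed to -0.091 with median scaling and -0.066 with quantile normalization and with the authors' values. It also reversed to -0.00505 with loess and -5.16e-04 in the upper part of the levels. Without members of the inducible lists it was -5.16e-04, and the cause was not tested. Dim genes are limited by background: the lowest level well above it was -5.29 on the PBS array and -4.92 on the miR-122 array.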

Other observations

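Gene families were grouped by symbol after the data were seen, over 263 families with at least 8 measured genes. The Gbp family of interferon-inducible GTPases had the highest median difference under the scaling used, 4.42 over 8 genes, and 3.48 to 4.42 over the scalings and background corrections. The Mcm family, which holds subunits of the replicative helicase, had the lowest, -1.17 over 10 genes, and -1.35 to -1.05 over the same settings. Outside interferon and replication genes, all 8 measured Sprr genes, which encode small proline-rich proteins of the cornified envelope, had positive differences between 0.17 and 2.69. Their median was 1.61, and 0.76 to 1.61 over these settings. Fabp genes, which encode fatty acid binding proteins, had a median of 1.03 over 9 genes, and 0.38 to 1.03 over them. The median levels of the Sprr and Fabp families were -3.12 and -3.02, in the dim part of the range, and close relatives within these and the Gbp family can share a probe.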
